A study of Mus musculus with 14 samples.

How the data were processed

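RNA labelled as mouse lymph node was measured on 14 one-colour Affymetrix arrays, with 3 untreated arrays, 2 arrays from 30 min and 2 arrays from 120 min after ionizing radiation for each of 2 genotypes, Atm+/+ (WT) and Atm-/- (KO). Groups, times and replicate letters were taken from the sample titles. The deposited values are one intensity per probe set and array on a linear scale, never negative, ranging from 0 to 15198.3. The software and settings that made them are not given in the sources used here. The mean of each array's values without the highest and lowest 2% was 150.1 on all 14 arrays, so each array had been scaled to a common target before deposit, as read from the values. The array medians lay between 61 and 80.4, and between 28.8% and 36.5% of an array's values lay below 32. For arrays of this kind the number of arrays, not a read depth, limits the precision.

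Values were taken as log2(value + 32). The medians of the 14 arrays spanned 0.273 on that scale, above the limit of 0.2 set in advance, so the log2 values were quantile normalized. Of 12488 probe sets, the 66 control probe sets were left out, and a probe set was tested when it lay above its array's own 40th percentile (38.3 to 55.28 in deposited intensity) on at least 2 arrays, which left 8938. Gene names came from the platform's annotation, updated through Entrez IDs. Over the whole array 10855 probe sets had 1 gene, 396 had several and 1237 had none. Of those with 1 gene, 10839 were found by Entrez ID, with 0 symbols changed. Among the tested probe sets 7960 had 1 gene, 303 had several and 675 had none, and probe sets with several genes were not named. The tested probe sets stood for 6541 genes. No genomic positions are given because the sources name no genome build.

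A model of 6 group means was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, with statmod 1.5.0 installed), so that 8 residual degrees of freedom, with 4.56 prior degrees of freedom, estimated the spread for every comparison. The comparisons were 30 and 120 min against untreated in each genotype, KO against WT untreated, KO against WT averaged over the 3 conditions, and the difference between the KO and WT responses at each time. WT at 120 min against WT at 30 min was added after seeing the data. p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets and called at an adjusted p under 0.05.

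The 28 gene and marker lists were fixed from general knowledge of the tissue and treatment. They held p53 targets (23 genes measured), NF-kB targets (28), immediate-early genes (24), interferon-stimulated genes (23), heat shock and stress genes (22), glucocorticoid-responsive genes (18), mitosis and G2/M genes (22), G1/S and replication genes (28), DNA double-strand break repair genes (18), apoptosis regulators (22), oxidative phosphorylation genes (37), cytosolic ribosomal proteins (25), neighbours of Atm (16) and sex-linked genes (3). The marker lists were those of B cells (15), plasma cells (9), T cells (17), immature thymocytes (6), NK and cytotoxic cells (8), macrophages and monocytes (16), neutrophils and myeloid precursors (11), dendritic cells (9), stroma and endothelium of lymph nodes (20), erythroid cells (8), adipocytes (12), skeletal muscle (17), salivary gland (11) and exocrine pancreas (8). Some genes belong to 2 lists, such as Ier3 to the NF-kB and immediate-early lists and Dusp1 to the immediate-early and glucocorticoid lists. A gene was represented by its probe set with the highest mean over all arrays. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and again with a correlation estimated from the data. Of the shifts that passed with the preset value, those that held with the estimate numbered 2 of 2 in WT at 30 min, 5 of 10 in WT at 120 min, 0 of 1 and 0 of 8 in KO at 30 and 120 min, 0 of 2 between untreated genotypes, 2 of 5 in the average over conditions, 1 of 3 and 3 of 7 in the differences of response at 30 and 120 min, and 1 of 8 in WT between the 2 times.

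The genes named per comparison were Atm, the 12 with the largest rise and the 12 with the largest fall among called probe sets whose groups did not overlap, with 1 probe set per gene and no probe set without a single gene, and 2 to 4 members per list by size of change. Named genes with a called rise in WT against untreated were also given in KO, while those named by smallest p in KO were not all given in WT. The condition on overlap was dropped for the differences of response and the average over conditions. Where fewer than 10 probe sets were called, the 10 with the smallest p were given. Genes named outside this rule, which are Glycam1, Cxcl13 and Madcam1, the single salivary genes and the immunoglobulin probe sets as a group, were chosen after their values were seen. List members given as examples without a call were those with large changes within their list.

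The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were median centring or no normalization between arrays, offsets of 16 and 64, a floor of 32 with no offset, no filter, a filter on the mean above the median probe set, the replicate letter as a block, only the groups compared in the fit, an intensity trend with a robust prior, array weights, an added fold limit of 1.5, and each array left out in turn, where the lone array of a group of 2 is assumed to vary like the other groups. For the lists they were the estimated correlation, fry, all probe sets of each gene and the block. Chosen after seeing the data were the fit without the 3 arrays of lowest mean correlation with the others (KO 30 min A at 0.908, WT untreated A at 0.925 and KO 120 min A at 0.929) and a muscle score, the median deviation of skeletal muscle markers on each array, as a covariate.

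The fit and the calls were tested on simulated log2 values for 8938 probe sets. The offset, normalization and filter were not part of that test. For WT at 120 min against untreated, 60% of probe sets changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with 12 false calls of 172. For the difference of the 120 min response, 11% of those changed by -1 and 83% of those changed by -2 were recovered, with 6 false calls of 100, so differences of response of about 1 on the log2 scale were mostly missed. Of 28 lists of random genes in those data, the unshifted ones gave 0 calls. The simulated values were not correlated between genes, so this does not test the preset correlation of the lists.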

Results

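Gene expression was measured on 14 Affymetrix arrays hybridised with RNA labelled as mouse lymph node. The arrays came from wild-type animals (WT, Atm+/+) and animals lacking Atm (KO, Atm-/-), the kinase that is activated by DNA double-strand breaks and starts the signalling that follows them. Each genotype had 3 untreated arrays, 2 arrays from 30 min after ionizing radiation (IR) and 2 arrays from 120 min after it. The radiation dose is not given in the sources used here. The number of arrays limits the precision. The median standard error of a log2 change was 0.232 for 2 irradiated against 3 untreated arrays, 0.138 for the genotype difference averaged over conditions and 0.328 for the difference between the 2 genotypes' responses. All changes are on the log2(value + 32) scale, which understates changes of genes with low values. Each is given ± its standard error from the limma fit, with the p adjusted over 8938 probe sets. Nothing in the labels says that the replicates are separate animals, so the p-values measure only the spread among these samples.

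Probe sets of salivary gland genes were among the highest values on all 14 arrays. Levels of different probe sets depend on the probes as well as on the transcripts, so the values given next do not compare amounts of RNA. Of the 11 measured genes of the salivary gland list, 8 lay in the top 1% of 12422 probe sets on every array. Prol1, a salivary mucin-like protein, had the highest mean of all probe sets, 11494 (range 7951 to 15198). The kallikrein Klk1 averaged 10823, the secreted carbonic anhydrase Car6 averaged 7364, salivary amylase Amy1 averaged 7044 and Egf averaged 6851. The median of the salivary list lay between 5567 and 9255 on single arrays. The median of 15 B cell markers lay between 57.3 and 153, and that of 17 T cell markers between 60.1 and 99.5. Glycam1, a mucin-like ligand made by the high endothelial venules of lymph nodes, lay between 151.4 and 876.5. It was chosen from its list after its values were seen. Which cells the changes described here come from was not measured.

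**Figure D1:**
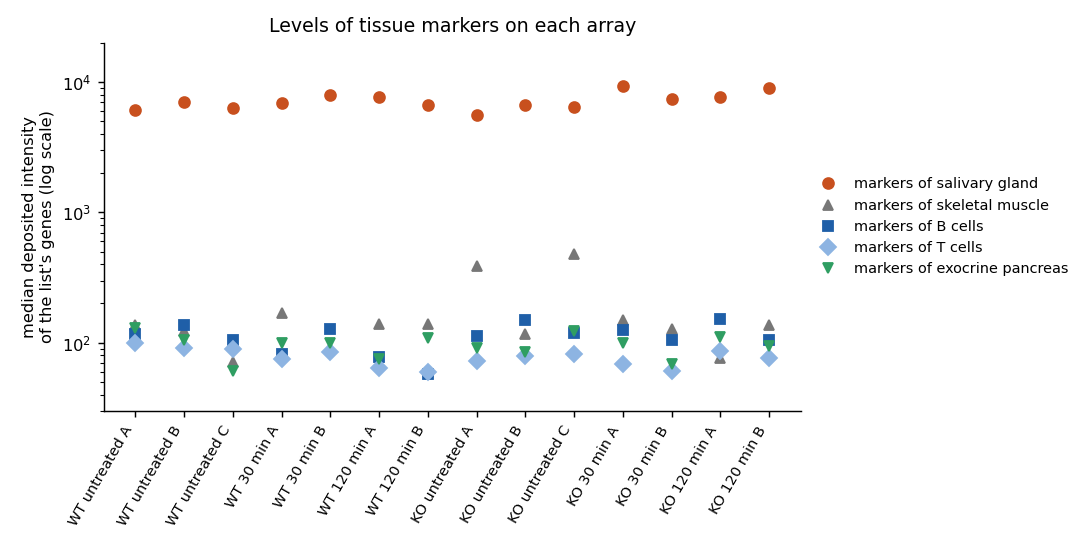
Median deposited intensity (log scale) of the genes of 5 marker lists on each of the 14 arrays, with 1 point per list and array. Salivary gland markers lie between 5567 and 9255 on every array. B cell markers lie between 57.3 and 153, T cell markers between 60.1 and 99.5 and skeletal muscle markers between 71.7 and 481.1. Levels of different probe sets do not compare amounts of RNA.

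Atm itself was read by 1 probe set at low values in both genotypes. The deposited intensities were 54.8, 34.5 and 8.1 on the untreated WT arrays, 5.5 and 34.2 on the WT arrays at 30 min, and 55.9 and 36.1 on the WT arrays at 120 min. In KO they were 44, 7.5 and 24 without treatment, 7.5 and 11.8 at 30 min, and 37.3 and 13 at 120 min. The KO minus WT difference averaged over the 3 conditions was -0.33 ± 0.22, with an adjusted p of 0.87. Where the probe set lies relative to the disrupted part of the gene is not given in the sources used here, so these values check nothing about the genotype labels. The 16 measured neighbours of Atm on its chromosome, a list fixed in advance, did not shift between untreated genotypes or at any other comparison tested.

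The first comparison asked which genes responded to IR within 30 min when Atm was present. At 30 min, 9 probe sets of 8 genes rose in WT and none fell, while 449 had an unadjusted p under 0.05 by limma against 446.9 from chance. The neutrophil-attracting chemokine Cxcl1, which has 2 probe sets, called the first and second here, rose by 2.73 ± 0.29 by the first (adjusted p = 0.000751), a 6.65-fold change. The AP-1 subunit Fos rose by 2.52 ± 0.21 (adjusted p = 9.6e-05), from 49.0, 46.1 and 42.1 on the untreated arrays to 416.1 and 416.0. The stress-induced gene Ier3 rose by 2.35 ± 0.18 (adjusted p = 7.98e-05), and Dusp1, a phosphatase that switches off MAP kinases, rose by 2.21 ± 0.19 (adjusted p = 9.6e-05). Nfkbia, which encodes the NF-kB inhibitor IkB-alpha and is itself an NF-kB target, rose by 1.5 ± 0.16 (adjusted p = 0.000751), while its second probe set was at 0.98 (adjusted p = 0.175). The zinc-finger factor Egr1 rose by 1.28 ± 0.16, the nuclear protein gene Ier2 by 1.17 ± 0.15, and Zfp36, whose product promotes decay of AU-rich mRNAs, by 1.70 ± 0.27. Glra1, the tenth by p, was at 1.41 ± 0.26 and did not pass (adjusted p = 0.107). All 9 called probe sets were higher on both irradiated arrays than on all 3 untreated ones, a separation that chance gives, in either direction, for 20% of probe sets. Of 24 measured immediate-early genes, 6 rose and 18 did not pass. Adjusted over the list alone, 10 rose, among them Atf3 at 1.34 and Junb at 1.19. The list shifted upward by limma's camera test (median 0.47, adjusted p = 1.66e-16, and adjusted p = 0.000666 with an estimated correlation). Of 28 measured NF-kB targets, Cxcl1, Ier3 and Nfkbia rose, and 6 did so adjusted over the list alone. That list also shifted upward (median 0.15, adjusted p = 0.000428, and adjusted p = 0.0491 with an estimated correlation). The p53 targets had a median of 0.17 and did not shift (adjusted p = 0.0944). Without array WT 30 min B the calls of Egr1 (adjusted p = 0.0971), Ier2 (0.174) and the second Cxcl1 probe set (0.12) ended. The call of Zfp36 ended in 9 of the 14 fits that each left out 1 array, with adjusted p up to 0.375 (without WT untreated A or B, WT 30 min A, WT 120 min A or B, KO untreated A, B or C, or KO 30 min B). The fit of only the groups compared ended the calls of Nfkbia (adjusted p = 0.14), Egr1 (0.163), Ier2 (0.333) and Zfp36 (0.539), and leaving out the 3 arrays of lowest correlation, an alternative chosen after seeing the data, ended those of Ier2 (0.0579) and Zfp36 (0.113). The Zfp36 call also ended with the replicate block (adjusted p = 0.0603 by limma), offset 16 (0.0527) and the muscle covariate (0.0583). It ended in 5 of 13 alternatives other than a single array left out. The 3' to 5' ratio of Gapdh, a sign of RNA quality, was 0.851 and 0.890 on the WT arrays at 30 min against 0.958, 0.902 and 1.01 on the untreated ones.

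**Figure D2:**
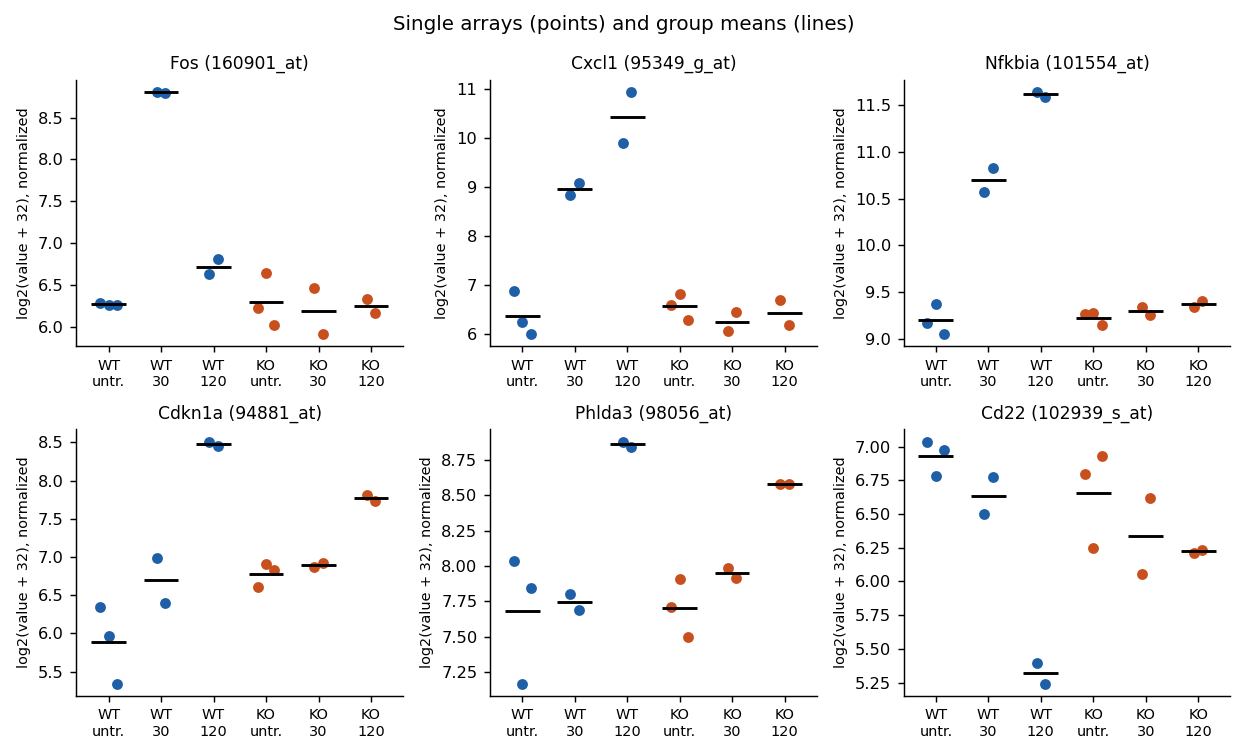
Normalized log2(value + 32) of 6 genes on single arrays (points) with group means (lines), WT in blue and KO in orange, for untreated arrays (n = 3) and arrays at 30 and 120 min after IR (n = 2 each). Fos peaks in WT at 30 min with a change of 2.52, Nfkbia reaches a change of 2.42 in WT at 120 min, and Cdkn1a is higher at 120 min by 2.59 in WT and 0.99 in KO.

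At 120 min after IR, 46 probe sets of 40 genes changed in WT, of which 42 rose and 4 fell, and 774 had an unadjusted p under 0.05 by limma. The second Cxcl1 probe set had the largest rise, 4.05 ± 0.32 (adjusted p = 5.66e-05), a 16.5-fold change. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases p21, rose by 2.59 ± 0.26 (adjusted p = 0.00044), from 52.0, 32.3 and 7.1 to 342.9 and 318.1. Nfkbia rose by 2.42 ± 0.16 (adjusted p = 1.52e-05) and Tnfaip3, which encodes the ubiquitin-editing enzyme A20, by 2.33 ± 0.23 (adjusted p = 0.00044). The NF-kB subunit gene Relb rose by 2.14 ± 0.28, Bcl3, an IkB-family coactivator, by 2.14 ± 0.27, and the TNF-induced gene Tnfaip2 by 2.12 ± 0.29. The adhesion molecule Icam1 rose by 2.10 ± 0.22, the lipopolysaccharide co-receptor Cd14 by 2.10 ± 0.24 and the apoptosis inhibitor Birc3 by 1.99 ± 0.27. The AP-1 subunit Junb rose by 1.98 ± 0.38 and the transcription factor Sox4 by 1.94 ± 0.29. Other probe sets of some of these genes did not pass, with that of Cdkn1a at 1.02 (adjusted p = 0.231), that of Sox4, which has the higher mean level, at 0.65 (adjusted p = 0.338) and that of Junb named at 30 min at 1.27 (adjusted p = 0.0684). Among the genes that fell, Cd22, an inhibitory receptor of B cells, fell by 1.62 (standard error 0.23, adjusted p = 0.0053). Atp5mpl, a small subunit of mitochondrial ATP synthase, fell by 1.09, and H2-Ob, a class II chain that modulates peptide loading in B cells, fell by 0.95.

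Single arrays moved these calls. The count of 46 became 30 without WT untreated A, 23 without WT untreated B, 17 without WT 120 min A and 13 without WT 120 min B. Without WT 120 min A the adjusted p was 0.0525 for Relb, 0.0874 for Tnfaip2, 0.106 for Sox4 and 0.0531 for Cd22. Without WT 120 min B it was 0.0507 for Relb, 0.0602 for Bcl3, 0.0834 for Birc3, 0.131 for Sox4 and 0.119 for Cd22. The calls of Junb, Atp5mpl and H2-Ob ended in 10, 11 and 12 of the 14 fits that each left out 1 array, with adjusted p up to 0.381, 0.576 and 0.567. Leaving out WT untreated B, KO untreated B, KO untreated C or KO 30 min A kept the Junb call. That of Atp5mpl was kept without WT 30 min A, WT 30 min B or KO 30 min B, and that of H2-Ob without KO 30 min A or KO 30 min B. The Cd22 call also ended with a floor and no offset (-1.49, adjusted p = 0.0848), and those of Junb, Atp5mpl and H2-Ob ended in 6, 8 and 5 of 13 alternatives of other kinds. Cxcl1, Cdkn1a, Nfkbia, Tnfaip3, Icam1 and Cd14 passed in all 14 of these fits.

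By group, 10 of 28 measured NF-kB targets rose in WT at 120 min, led by Cxcl1, Nfkbia, Tnfaip3 and Relb, and 18 did not pass. Adjusted over the list alone, 11 rose and Ltb fell. The list shifted upward (median 0.40, adjusted p = 3.4e-19, and adjusted p = 0.000458 with an estimated correlation). Of 23 measured p53 targets, Cdkn1a and Phlda3, a p53-induced inhibitor of Akt, rose and 21 did not pass. Phlda3 was at 1.18 ± 0.23 (adjusted p = 0.043), and its call ended in 12 of the 14 fits that each left out 1 array (all but KO 30 min A and WT untreated A), with adjusted p up to 0.352, and in 6 of 13 alternatives of other kinds. Adjusted over the list alone, 6 p53 targets rose, among them Btg2 at 1.15, Mdm2 at 1.07 and Ccng1 at 0.70. The p53 list shifted upward (median 0.43, adjusted p = 8.47e-07, and adjusted p = 0.0181 with an estimated correlation). Of 24 immediate-early genes, Ier3 (1.56 ± 0.18) and Dusp1 (1.13 ± 0.19) rose, and 8 rose adjusted over the list alone. Their median was 0.42 (adjusted p = 6.06e-10, and adjusted p = 0.00229 with an estimated correlation). Dusp1 and Cebpd (1.05 ± 0.17), both also induced by glucocorticoids, were the 2 risen members of 18 measured glucocorticoid-responsive genes, a list that did not shift (median 0.19, adjusted p = 0.0558). The Dusp1 call ended without WT untreated B (adjusted p = 0.0666), WT 120 min A (0.0834) or WT 120 min B (0.307), and that of Cebpd without WT 120 min B (0.264). The fit of only the groups compared also ended both (adjusted p = 0.125 and 0.146), the muscle covariate that of Dusp1 (0.0648) and the replicate block that of Cebpd (0.0523).

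Lymphocyte markers were lower in WT at 120 min. Of 15 measured B cell markers, Cd22 fell and 14 did not pass, and 6 fell adjusted over the list alone, among them Fcer2a at -1.22, Cd79b at -1.12 and Cd79a at -0.87. The B cell list shifted downward (median -0.51, adjusted p = 5.15e-08, and adjusted p = 0.0472 with an estimated correlation). No T cell marker passed singly, but all 17 measured were below the untreated level, with Cd3e at -0.94 and Cd2 at -0.74. The T cell list shifted downward (median -0.39, adjusted p = 5.31e-06, and adjusted p = 0.0379 with an estimated correlation). Of the node markers that lymphocytes do not make, Glycam1 was at -1.10 ± 0.31 (adjusted p = 0.263), Madcam1 at -0.10 ± 0.24 (adjusted p = 0.945) and Cxcl13 at 0.33 ± 0.33 (adjusted p = 0.838). The 3' to 5' ratio of Gapdh was lower on the same arrays, at 0.891 and 0.723 against 0.958, 0.902 and 1.01 on the untreated ones, and that of beta-actin averaged 1.37 against 1.46. Skeletal muscle markers were higher there (median 0.58, adjusted p = 0.00363, but adjusted p = 0.667 with an estimated correlation). Salivary gland markers did not shift (median 0.06, adjusted p = 0.722), nor did markers of stroma and endothelium (0.06, adjusted p = 0.337). Of 23 interferon-stimulated genes none passed, 1 fell adjusted over the list alone (Psmb9, an immunoproteasome subunit, at -0.68), and the list shifted downward (median -0.34, adjusted p = 2.71e-05, but adjusted p = 0.108 with an estimated correlation). Smaller downward shifts of mitosis and G2/M genes (median -0.21, adjusted p = 0.00926), oxidative phosphorylation (-0.16, 0.0132) and adipocyte markers (-0.30, 0.0132) were lost with an estimated correlation (adjusted p = 0.608, 0.615 and 0.608).

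The remaining lists did not shift in WT at 120 min. Heat shock and stress genes had a median of 0.10 (adjusted p = 0.337), apoptosis regulators 0.12 (0.219), G1/S and replication genes 0.01 (0.923), double-strand break repair genes -0.09 (0.757), cytosolic ribosomal proteins -0.09 (0.249), neighbours of Atm -0.05 (0.345) and sex-linked genes -0.05 (0.955). Markers of plasma cells had a median of -0.15 (0.337), immature thymocytes -0.11 (0.923), NK and cytotoxic cells -0.14 (0.722), macrophages and monocytes 0.01 (0.943, tested direction downward), neutrophils and myeloid precursors 0.02 (0.943), dendritic cells -0.03 (0.923), erythroid cells -0.13 (0.602) and exocrine pancreas -0.02 (0.923).

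**Figure D3:**
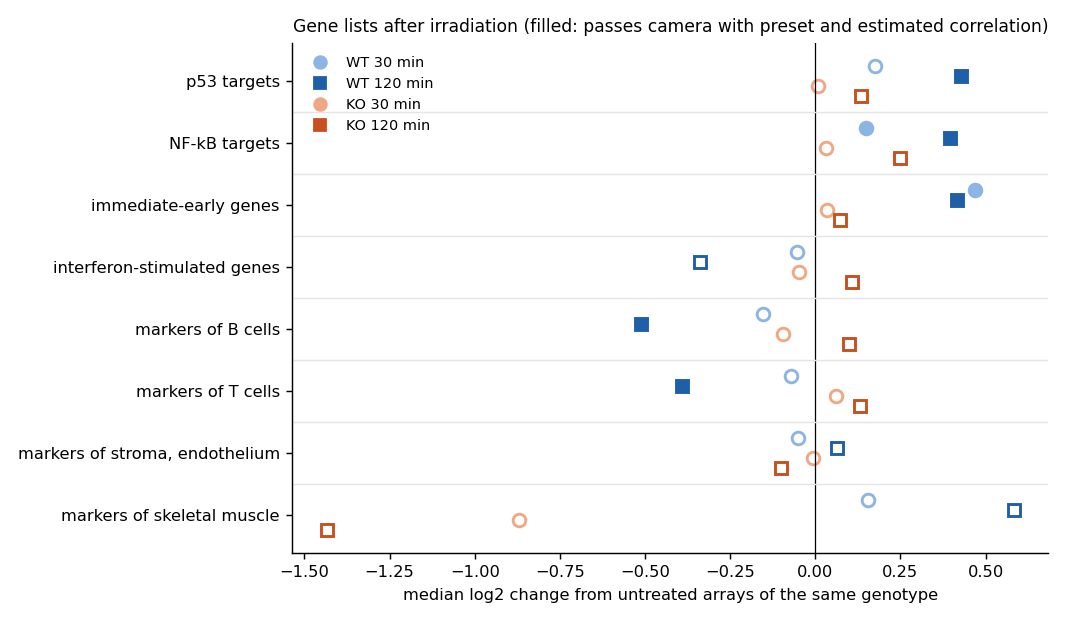
Median log2 change of the measured members of 8 gene lists at 30 and 120 min after IR against untreated arrays of the same genotype (2 against 3 arrays), with filled symbols for lists that pass camera's test with both the preset and an estimated correlation. In WT at 120 min NF-kB targets lie at 0.40 and B cell markers at -0.51, and in KO at 120 min NF-kB targets lie at 0.25 and skeletal muscle markers at -1.43.

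WT arrays at 120 min were set against WT arrays at 30 min, a comparison chosen after seeing the data, to ask which genes differed between the 2 times. Relb rose by 2.45 ± 0.30 (adjusted p = 0.00755), Tnfaip2 by 2.08 ± 0.32, Icam1 by 2.03 ± 0.24 (adjusted p = 0.00684), Bcl3 by 1.89 ± 0.29 and Cdkn1a by 1.78 ± 0.28 (adjusted p = 0.033, with its second probe set at 1.25 and an adjusted p of 0.258). Cd14 rose by 1.62, the probe set named D17H6S56E-5 by 1.43, the chemokine Cx3cl1 by 1.19 (second probe set at 0.59, adjusted p = 0.92) and Rasal1, a Ras-inactivating protein, by 1.12. Fos fell by 2.08 (standard error 0.23, adjusted p = 0.00624) and Ier2 fell by 1.01. NF-kB targets shifted upward (median 0.49, 3 rose, 9 adjusted over the list alone, adjusted p = 1.35e-11, and adjusted p = 0.00287 with an estimated correlation). The p53 targets had a median of 0.24 (adjusted p = 0.00123, but adjusted p = 0.146 with an estimated correlation). Of the immediate-early genes, Fos and Ier2 fell, and the list's downward shift (median -0.03, mean -0.20, adjusted p = 0.0278) was lost with an estimated correlation (adjusted p = 0.199). These 11 calls rest on all 4 arrays compared, since leaving out 1 of them leaves a lone array at that time. Over the 14 fits that each left out 1 array the change ranged from 1.98 to 2.08 for Icam1 and 2.33 to 2.57 for Relb. It ranged from -2.17 to -1.97 for Fos and from 1.41 to 2.36 for Bcl3. The count became 0 when only the groups compared were fitted. Other alternatives, that fit included, ended the calls of Bcl3 in 5 of 12, Cdkn1a, Cd14, D17H6S56E-5 and Rasal1 in 5 of 13 each, Cx3cl1 in 6, Ier2 in 7 of 13 and Tnfaip2 in 2 of 12. The count was 4 without WT untreated C, KO untreated B, KO untreated C, KO 120 min A or KO 120 min B, and 3 without KO untreated A.

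The same times were tested in KO to ask which changes occurred without Atm. At 30 min no probe set passed in KO by limma, while 749 had an unadjusted p under 0.05 against 446.9 from chance, and the median absolute change over all probe sets was 0.196, against 0.168 in WT. The smallest p values belonged to Slc26a2, a sulfate transporter, at 1.41 ± 0.21 (adjusted p = 0.0872), and Met, the hepatocyte growth factor receptor, at 1.15 ± 0.17 (adjusted p = 0.0872). The others among the 10 smallest were Barx1 at 1.23, Rasal1 at 0.91, Nudt5 at 1.01, Dnajc11 at 1.22, Commd3 at 1.04, Slc7a9 at -0.998, Sugt1 at -0.92 and a probe set with no single gene name here at -0.89. None of these is a member of the fixed response lists. The genes that rose in WT at 30 min were near their untreated level, with Fos at -0.10, the first Cxcl1 probe set at -0.16, Ier3 at 0.04, Nfkbia at 0.07, Dusp1 at 0.34, Zfp36 at -0.14, Egr1 at 0.37 and Ier2 at 0.24. NF-kB targets (median 0.03, adjusted p = 0.891) and immediate-early genes (0.04, 0.431) did not shift. The 1 list that shifted was skeletal muscle (median -0.87, adjusted p = 6.71e-07, but adjusted p = 0.899 with an estimated correlation). The count of 0 became 240 without KO 30 min B, which left KO 30 min A, the array of lowest mean correlation with the others (0.908), alone at that time. It became 1 without WT 120 min A or WT 120 min B.

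At 120 min again no probe set passed in KO by limma, with 645 at an unadjusted p under 0.05. The smallest p belonged to a probe set with no gene name here, at 1.72 ± 0.24 (adjusted p = 0.0927). It was followed by Kng1 at 1.22, Defa35 at 0.91, Kcnk1 at -1.11, the muscle calcium buffer Pvalb at -1.77, Pip4k2c at -1.43, Capn3 at 1.04, the mast cell protease Mcpt1 at 1.38, a probe set with no single gene name here at -0.65 and Slc25a51 at -0.81. Adjusted over the list alone, 2 of 23 p53 targets rose in KO, Cdkn1a at 0.99 ± 0.26 and Phlda3 at 0.87 ± 0.23 (adjusted p = 0.027 for each). Cdkn1a went from 67.2, 91.5 and 81.7 to 194.1 and 177.5, while its second probe set was at 0.51 (adjusted p = 0.762 by limma). Mdm2, the p53 ubiquitin ligase, was at 0.94. The p53 list shifted upward (median 0.13, adjusted p = 0.0284), as did NF-kB targets (0.25, 0.00274), interferon-stimulated genes (0.11, 0.0157), macrophage markers (0.27, 0.00742) and neutrophil markers (0.37, 0.0157). All of these shifts were lost with an estimated correlation (adjusted p = 0.245, 0.182, 0.427, 0.186 and 0.245). Macrophage markers lay at 0.49 above the mean of all arrays on KO 120 min A and 0.05 on KO 120 min B, against -0.06, 0.04 and -0.01 untreated, and neutrophil markers at 0.36 and 0.05 against -0.06, -0.01 and -0.23. Without the 3 arrays of lowest correlation, of which KO 120 min A is 1, these 2 shifts ended (adjusted p = 0.499 and 0.505), as did those of p53 targets (0.223) and NF-kB targets (0.237). Immediate-early genes (0.07, 0.907), B cell markers (0.10, 0.418), T cell markers (0.13, 0.169) and salivary gland markers (0.003, 0.989) did not shift. Oxidative phosphorylation (-0.11, 0.00964) and immature thymocyte markers (-0.19, 0.0284) shifted downward, also not with an estimated correlation (adjusted p = 0.596 and 0.186) or without those 3 arrays (adjusted p = 0.872 and 0.499). On these arrays skeletal muscle markers had a median of -1.43 (adjusted p = 3.83e-17, but adjusted p = 0.186 with an estimated correlation), and 13 of 17 fell adjusted over the list alone. The 3' to 5' ratio of Gapdh was 0.857 and 0.777 on these arrays against 0.896, 0.867 and 0.976 on the untreated KO arrays. The count of 0 became 11 without KO 120 min B and 2 without KO untreated B.

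Whether a response differed between genotypes was tested by the interaction of genotype and IR. At 30 min the response of 7 probe sets of 6 genes differed. The KO minus WT difference was -2.90 ± 0.46 for the second Cxcl1 probe set (adjusted p = 0.0393), -2.63 ± 0.29 for Fos (adjusted p = 0.00388), -2.31 ± 0.25 for Ier3 (adjusted p = 0.00388), -1.87 ± 0.26 for Dusp1 (adjusted p = 0.0209) and -1.44 ± 0.22 for Nfkbia (adjusted p = 0.0393, with its second probe set at -0.85 and an adjusted p of 0.789). Barx1, a homeobox transcription factor, differed in the other direction (1.91 ± 0.29, adjusted p = 0.0322). It was already at -0.85 in untreated KO against WT (adjusted p = 0.634 by limma), which enters that difference. Immediate-early genes shifted downward as a list (median -0.27, 3 passed and 9 adjusted over the list alone, adjusted p = 1.44e-07, and adjusted p = 0.0104 with an estimated correlation). NF-kB targets did so only with the preset correlation (median -0.29, adjusted p = 0.011, but adjusted p = 0.182 with an estimated correlation), as did skeletal muscle markers (median -1.12, adjusted p = 2e-06, but adjusted p = 0.907 with an estimated correlation). Fos and Ier3 passed in all 14 fits that each left out 1 array. Leaving out the 3 arrays of lowest correlation, which left 5 residual degrees of freedom in place of 8, ended all 7 calls. The differences were then -3.05 ± 0.36 for Fos and -2.38 ± 0.30 for Ier3 (adjusted p = 0.0575 for each). Counting that fit, alternatives other than a single array left out ended the call of Nfkbia in 8 of 13 (offset 16 at an adjusted p of 0.0669, the block at 0.0896), the first Cxcl1 probe set in 4 and the second in 7 of 13, Dusp1 in 4 of 13 and Barx1 in 7 of 12. The count of 7 became 28 without KO 30 min B, 4 without WT 30 min A, 3 without KO untreated C or KO 30 min A, and 2 without WT untreated C, WT 30 min B, KO untreated A or KO untreated B. In these fits the adjusted p reached 0.151 for Dusp1, 0.243 for Nfkbia and the second Cxcl1 probe set, 0.155 for the first and 0.205 for Barx1.

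At 120 min the response of 12 probe sets differed between genotypes, and all 12 differences were negative. The difference was -4.17 ± 0.46 for the second Cxcl1 probe set (adjusted p = 0.00283), -2.27 ± 0.22 for Nfkbia (adjusted p = 0.00179), -2.18 ± 0.33 for Cd14 (adjusted p = 0.0265) and -2.04 ± 0.33 for Tnfaip3 (adjusted p = 0.0348). It was -2.16 for D17H6S56E-5, -1.81 for Icam1, -1.65 for Cx3cl1, -1.64 for Dusp1 and -1.52 for Cebpd. A second Cx3cl1 probe set was at 0.42 (adjusted p = 0.907), with a WT change of 0.24. Of 28 NF-kB targets 4 passed, and 12 did so adjusted over the list alone, with 1 more in the other direction. The NF-kB list shifted downward (median -0.37, adjusted p = 3.31e-08, and adjusted p = 0.0107 with an estimated correlation), as did immediate-early genes (median -0.39, adjusted p = 1.1e-06, and adjusted p = 0.0111 with an estimated correlation). The p53 list did so only with the preset correlation (median -0.27, adjusted p = 0.0295, but adjusted p = 0.206 with an estimated correlation), with Cdkn1a at -1.61 (adjusted over the list alone, p = 0.0187). Cdkn1a was already at 0.90 in untreated KO against WT (adjusted p = 0.634 by limma), which enters that difference. Its second probe set had a difference of -0.51 (adjusted p = 0.886). T cell markers differed in the other direction (median 0.59, adjusted p = 2.59e-06, and adjusted p = 0.0451 with an estimated correlation), with Cd3e at 1.78. Cd3e and the median of the T cell list already lay lower in untreated KO than in WT, which enters these differences. B cell markers (median 0.63, adjusted p = 2.26e-07) and interferon-stimulated genes (median 0.57, adjusted p = 2.97e-07) differed in the same direction as T cell markers only with the preset correlation (adjusted p = 0.0589 for each with an estimated correlation). Skeletal muscle markers moved with these groups (median -1.995, adjusted p = 6.61e-16, but adjusted p = 0.112 with an estimated correlation). These probe sets of Cxcl1 and Nfkbia passed in all 14 fits that each left out 1 array. The muscle covariate ended all 12 calls, with wider standard errors, at -4.57 ± 0.66 for Cxcl1 and -2.34 ± 0.33 for Nfkbia (adjusted p = 0.0523 for each). Leaving out the 3 arrays of lowest correlation ended the Nfkbia call (-2.16 ± 0.30, adjusted p = 0.0518) and kept that of Cxcl1 (-4.73 ± 0.45, adjusted p = 0.0112). Both alternatives were chosen after seeing the data. Counting them, alternatives other than a single array left out ended the call of Icam1 in 8 of 12 (offset 16 at an adjusted p of 0.139, the block at 0.133), Tnfaip3 in 6 of 12 (offset 16 at 0.176), Cd14 in 4 of 13, and Cx3cl1, Dusp1 and Cebpd in 3 of 13 each. The block ended those of Cd14 (0.0752), Cx3cl1 (0.0752), Dusp1 (0.0789) and Cebpd (0.0734). The count of 12 became 6 without WT untreated A or WT untreated C, 5 without WT 120 min B, 4 without KO untreated A or KO 120 min A, and 3 without WT 120 min A or KO untreated C. In these fits the adjusted p reached 0.222 for Cd14, 0.121 for D17H6S56E-5, 0.261 for Tnfaip3 and Cebpd, 0.308 for Icam1, 0.139 for Cx3cl1 and 0.289 for Dusp1.

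The probe sets called in WT were then followed in KO. The 9 that rose at 30 min had a median change of 2.21 in WT, a value biased away from 0 because they were chosen in WT, and of 0.04 in KO (0.13 and 0.03 on the single KO arrays). None was called in KO by limma, with 1 at an unadjusted p under 0.05. Their interaction passed for 6 over all probe sets. It contains the WT change by which they were chosen, so it was not counted within this list. The 42 that rose at 120 min had a median of 1.58 in WT, with the same bias, and 0.09 in KO (0.11 and 0.04 on the single arrays). None was called in KO over all probe sets by limma, and 7 had an unadjusted p under 0.05. Adjusted over the list alone, 3 passed, namely the unnamed probe set of smallest p given above (adjusted p = 0.000435), Cdkn1a and Phlda3 (adjusted p = 0.0329 for each). The change was smaller in KO than in WT for 41 of the 42, a count with the same bias. The interaction passed for 12 over all probe sets. The 4 that fell in WT at 120 min had medians of -1.02 in WT and -0.20 in KO. Across all 8938 probe sets, which are not independent replicates, the WT and KO changes share no arrays and correlated weakly, with r = 0.0809 and rho = 0.0779 at 30 min and r = 0.0396 and rho = 0.0809 at 120 min.

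**Figure D4:**
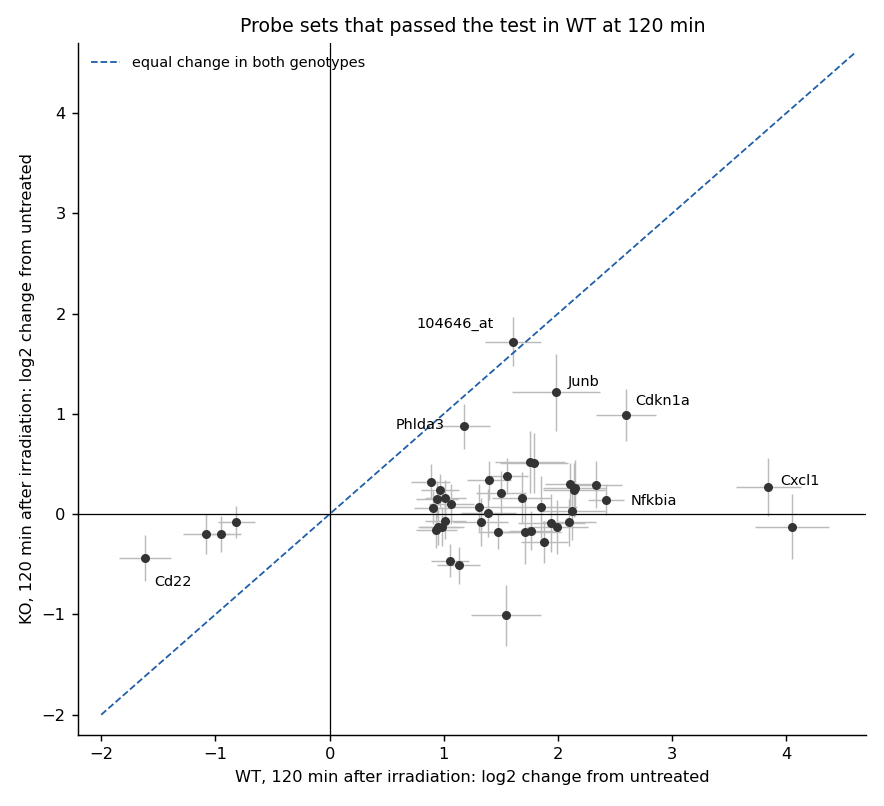
Log2 change at 120 min after IR in WT (horizontal axis) and KO (vertical axis), each 2 irradiated against 3 untreated arrays, with 1 point per probe set that passed in WT and bars for the standard errors. The 42 probe sets that rose in WT have a median of 1.58 in WT and 0.09 in KO, and 41 of them have a smaller change in KO.

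The genotypes were compared without irradiation to ask what lacking Atm changed at rest. No probe set passed by limma, with 490 at an unadjusted p under 0.05 against 446.9 from chance and a smallest adjusted p of 0.634. The 10 smallest p values belonged to the long noncoding RNA Tug1 (-1.32 ± 0.25), the glutathione transferase Gsta4 (1.10 ± 0.21), Hpca (-0.78), Kng1 (-0.998), Smap2 (-0.71), Barx1 (-0.85), muscle creatine kinase Ckm (1.51), Pvalb (1.53), Kcnk7 (0.72) and Hgfac (0.87). T cell markers were lower in KO (median -0.34, adjusted p = 0.000384, but adjusted p = 0.169 with an estimated correlation), with Cd3e (-1.28) and the interleukin-7 receptor Il7r (-0.59) lower adjusted over the list alone. Skeletal muscle markers were higher in KO (median 1.40, adjusted p = 2.44e-22, but adjusted p = 0.169 with an estimated correlation), and 14 of 17 were so adjusted over the list alone, with the calcium pump Atp2a1 at 2.26 and skeletal actin Acta1 at 2.03. The muscle level differed among single arrays of 1 group. It was 1.16, 0.04 and 1.30 above the mean of all arrays on the untreated KO arrays, and -0.15, -0.46 and -0.79 on the untreated WT arrays. Without KO untreated B the count of 0 became 7.

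**Figure D5:**
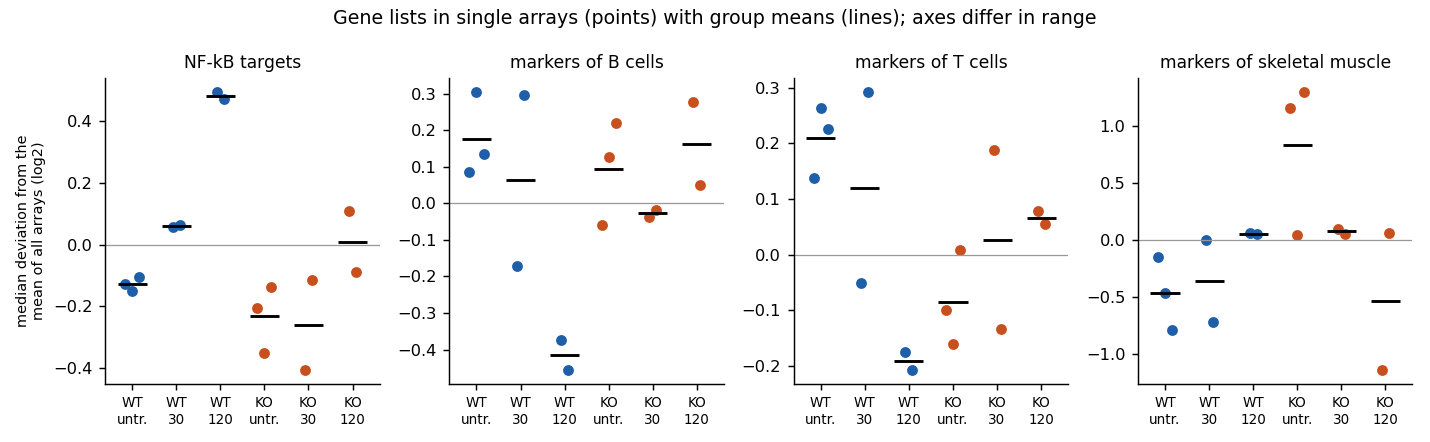
Median log2 deviation of the members of gene and marker lists from their mean over all 14 arrays, for each array, grouped by genotype and condition. Skeletal muscle markers lie at 1.16, 0.04 and 1.30 on the untreated KO arrays and at -1.14 and 0.06 on the KO arrays at 120 min.

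Averaged over the 3 conditions, 15 probe sets of 12 genes differed between genotypes, 7 arrays against 7, of which 14 were lower in KO and 1 was higher. The first Cxcl1 probe set was lower by -2.31 ± 0.17 (adjusted p = 6.26e-05), Tnfaip3 by -1.34 ± 0.14 (adjusted p = 0.00046), Ier3 by -1.21 ± 0.11, Nfkbia by -1.21 ± 0.09 (adjusted p = 6.35e-05), Dusp1 by -1.13 ± 0.11 and Fos by -1.02 ± 0.12 (adjusted p = 0.00248). Icam1 (-0.78), D17H6S56E-5 (-0.75), Ier2 (-0.70) and Egr1 (-0.57) were also lower. Among immunoglobulin genes, Igha, the IgA heavy chain, was at -1.80 ± 0.25 (adjusted p = 0.0072), while its second probe set was at -0.68 (adjusted p = 0.111). Ighm, the IgM heavy chain, was lower by 1 of its 11 tested probe sets (-1.40 ± 0.20, adjusted p = 0.0081) and higher by another (1.12 ± 0.18, adjusted p = 0.0211). Immediate-early genes (median -0.32, 5 lower, 10 adjusted over the list alone, adjusted p = 3.04e-17, and adjusted p = 0.000507 with an estimated correlation) and NF-kB targets (median -0.27, 5 lower, 12 adjusted over the list alone, adjusted p = 8.79e-16, and adjusted p = 0.000507 with an estimated correlation) were lower in KO. Glucocorticoid-responsive genes (median -0.14, adjusted p = 0.00319), B cell markers (0.19, 0.00314) and skeletal muscle markers (0.34, 0.000339) shifted only with the preset correlation (adjusted p = 0.345, 0.491 and 0.665 with an estimated correlation). Because the average includes the irradiated arrays, it holds the differences in response given above. For the called Igha and the lower Ighm probe set no difference of response passed. In untreated KO against WT they were at -1.37 and -1.14 (adjusted p = 0.662 and 0.634 by limma). Their differences of response were -0.90 and -0.76 at 30 min, and -0.39 and 0.0083 at 120 min. The count of 15 became 43 without KO 30 min B, and 9 without the 3 arrays of lowest correlation, which ended the calls of Igha (adjusted p = 0.117), Ier2 (0.117) and the lower Ighm probe set (0.121). Leaving out WT 120 min B ended the call of the lower Ighm probe set (adjusted p = 0.0529), and the calls of Icam1, D17H6S56E-5 and Egr1 ended in 10, 10 and 11 of the 14 fits that each left out 1 array, with adjusted p up to 0.167. They were kept for Icam1 without WT untreated A, KO untreated A, KO 30 min B or KO 120 min A, for D17H6S56E-5 without WT untreated B, KO untreated B, KO 30 min A or KO 30 min B, and for Egr1 without WT untreated A, KO 30 min A or KO 30 min B. The replicate block also ended the calls of Icam1 (adjusted p = 0.111), D17H6S56E-5 (0.0806) and Egr1 (0.111), the muscle covariate ended them at 0.199, 0.199 and 0.121, and offset 16 ended those of Icam1 (0.0815) and D17H6S56E-5 (0.0627). Leaving out the 3 arrays of lowest correlation ended the calls of Icam1, D17H6S56E-5 and Egr1 too, with differences of -0.81, -0.62 and -0.63.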

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

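Of the tests weighed here, those of unirradiated KO arrays, of the need for Atm, of the spread of the KO arrays at 30 min, of the share of node tissue and of the salivary gland markers were chosen only after the result was seen, while those of the spread of the KO arrays at 120 min, of quantile normalization and of other splits of the arrays were written before.

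The response to IR differed between the genotypes for 15 probe sets, 4 of them at both times, and in 4 list tests, which drew attention because the test of the difference itself passed. At 30 min the KO minus WT differences were -2.89 and -2.90 for the first and second probe sets of Cxcl1, -2.63 for Fos, -2.31 for Ier3, -1.87 for Dusp1, -1.44 for Nfkbia and 1.91 for Barx1. Untreated, Barx1 was at -0.85 in KO against WT, which enters its difference. The immediate-early list differed with an adjusted p of 0.0104 with an estimated correlation. At 120 min they were -3.57 and -4.17 for the same Cxcl1 probe sets, -2.56 for a probe set with no gene name here, -2.27 and -1.93 for the 2 probe sets of Nfkbia, that given at 30 min and another, -2.18 for Cd14, -2.16 for D17H6S56E-5, -2.04 for Tnfaip3, -1.81 for Icam1, -1.65 for Cx3cl1, -1.64 for Dusp1 and -1.52 for Cebpd. The lists that differed at 120 min with an estimated correlation were NF-kB targets (adjusted p = 0.0107), immediate-early genes (0.0111) and T cell markers (0.0451). Of these, only the T cell list had a higher response, not level, in KO than in WT.

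The first pattern weighed is that the probe sets that rose in WT after IR changed little in KO, although more probe sets had an unadjusted p under 0.05 at 30 min in KO (749) than in WT (449). Spread of the KO arrays is argued against at 120 min by 31 of the 42 probe sets that rose in WT (29 with the spread of the KO arrays alone), and at 30 min by 8 of 9 (7 with that spread), whose upper 95% bound in KO lay below the midpoint between 0 and their WT change, which is biased away from 0 by the choice. For unirradiated KO arrays at 120 min, 3 of the 42 were called in KO adjusted over the list alone, among them Cdkn1a. The second Cdkn1a probe set was at 0.51 in KO (adjusted p = 0.762 by limma). These calls do not exclude unirradiated arrays, since the 42 were chosen with the pooled spread that also gives the KO standard errors. The labels also name no unirradiated arrays from 120 min, so a change unrelated to IR cannot be told apart. For the KO arrays at 30 min the same test called 0 of 9, so arrays that were not irradiated and an absent early response cannot be told apart there. A response that needs Atm is a hypothesis that may account for the 120 min data, where NF-kB targets, a list fixed in advance, differed between genotypes (adjusted p = 0.0107 with an estimated correlation).

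The second pattern is that B and T cell markers, 32 genes together, were lower in WT at 120 min, with a median of -0.42. Quantile normalization is argued against, since the median relative to all probe sets was -0.45 with the values as deposited. A smaller share of node tissue on those arrays stays open, since 3 node markers that lymphocytes do not make parted (Glycam1 -1.10, Madcam1 -0.10, Cxcl13 0.33, median -0.10), which leaves a smaller share and a change within lymphocytes not to be told apart. That the fall needs Atm stays open too, since the response of T cell markers differed between genotypes (adjusted p = 0.0451) but their median was already -0.34 in untreated KO against WT, which enters that difference, and B cell markers missed the threshold (0.0589).

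The third pattern is the high values of salivary gland probe sets on every array. Of 9 salivary markers other than Krt8 and Krt18, 8 were in the top 1% of probe sets on all 14 arrays, while the median percentile of exocrine pancreas markers was at most 65.3. Prol1, Klk1, Smr3a and Klk1b22 of this list ranked 1, 2, 9 and 12 by mean value. Brightness unrelated to the tissue would put only a small share of a list fixed in advance in the top 1%. Krt8 and Krt18 were set aside after the values were seen, and the 8 are also 8 of the 11 measured genes of the whole list. They therefore argue against it as the only cause for these markers as a set. It is not excluded, because no array of another tissue was measured. How much of the RNA came from salivary gland cannot be read, because levels of different probe sets cannot be compared. The test of whether node tissue was also present rested on the single gene Glycam1, whose lowest percentile on any array was 70.3. The median percentile of B cell markers lay between 44.7 and 70.4 on single arrays, and that of T cell markers between 45.5 and 58.3. The question stays open, because levels of different probe sets cannot be compared. No biological explanation of this pattern was tested, since no group of the design separates it.

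For the average over conditions, 2 of 100 splits drawn from the 360 within conditions gave at least the 15 calls of the real one, itself included. The highest of the others also gave 15. That share is under 0.05 and argues against chance assignment of the genotypes among these arrays. It does not exclude it, because another split tied the real one. Nothing in the labels says that the arrays are separate animals, so chance among animals was not tested. For the untreated arrays the real split gave 0 calls and the highest of the others 1, all 10 splits gave at least as many as the real one, and 10 splits are too few for a share under 0.05.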

How the results depend on the processing

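The muscle covariate and the fit without the 3 lowest-correlation arrays were chosen after seeing the data. Unless stated, the cause of a move was not tested. Of the 68 calls of named genes, 1366 of 1820 values over all alternatives stayed past the threshold, 454 did not and 0 changed direction. Of 34 named genes below it, 877 of 890 values stayed below and 13 passed. Of the 46 list shifts, 14 held with an estimated correlation, 20 with fry's directional and 29 with its mixed test, 40 with all probe sets of each gene, 44 with the replicate block, 38 without the 3 arrays and 28 with the muscle covariate. 2 turned direction, oxidative phosphorylation in KO at 120 min without the 3 arrays (adjusted p = 0.872) and skeletal muscle averaged over conditions with the muscle covariate, which removes that signal by construction (adjusted p = 0.896). Lists were not retested with single arrays left out. Low signal limits what can be seen, since up to 36.5% of an array's values lay below the offset.

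Calls moved by over 1.5 times as follows. In WT at 30 min the fit of only the groups compared, with fewer degrees of freedom, gave 5. In WT at 120 min it gave 21, the replicate block 25 and the muscle covariate 25. In KO at 120 min array weights and the filter on the mean each gave 1, as did the calls in KO among probe sets risen in WT at 120 min. For the difference at 30 min offset 16 and the floor gave 4, the block, the groups compared, array weights and the muscle covariate 3, and leaving out the 3 arrays 0. For that at 120 min offset 64 gave 20, array weights 21, the block 5, leaving out the 3 arrays 4 and the muscle covariate 0. For WT at 120 against 30 min offset 16 gave 3, offset 64 21, the block and the muscle covariate 4, the groups compared 0, trend and robust prior 24 and array weights 23. Averaged over conditions, leaving out the 3 arrays gave 9. The median KO change of the probe sets risen in WT was -0.0728 (30 min) and 0.011 (120 min) without the 3 arrays, -0.10 and 0.16 with only the groups compared, and -0.00682 at 120 min with the block. The WT and KO correlation was -0.00663 (30 min) and -0.154 (120 min) with the muscle covariate, and 0.18 and 0.141 with the block.

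Leaving out 1 array at a time gave 6 to 10 calls in WT at 30 min, 13 to 55 in WT at 120 min, 0 to 240 in KO at 30 min, 0 to 11 in KO at 120 min, 0 to 7 between untreated genotypes, 10 to 43 averaged over conditions, 2 to 28 and 3 to 18 for the differences at 30 and 120 min, and 0 to 16 for WT at 120 against 30 min. The median KO change of the probe sets risen in WT ranged from -0.0584 to 0.13 (30 min) and -0.0795 to 0.22 (120 min), the calls in KO among them from 0 to 1 and 0 to 0, and the correlation from 0.0292 to 0.136 and -0.0169 to 0.0856.

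The replicate letters showed no sign of pairing the arrays. Deviations from the group means correlated with a median r of -0.0172 over 31 pairs of the same letter, 0 of them over 0.1, and 0.0161 over 50 pairs of different letters. In a group of 2 arrays the deviations are mirror images, so the pairs are not independent and weak pairing cannot be excluded.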

Other observations

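Immunoglobulin probe sets, taken as a group after their values were seen and not tested as one, had opposite medians in the 2 genotypes at 120 min after IR. The 52 tested probe sets had a median of -0.52 in WT and 0.72 in KO. The median difference of response was 1.12, with 48 of 52 positive and 0 called. The 8 other plasma cell markers had a median difference of response of 0.011. Probe sets of 1 gene are not independent, and 11 of the 52 read Ighm.

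The unnamed probe set with the smallest p in KO at 120 min was alike in both genotypes, at 1.61 ± 0.24 in WT and 1.72 ± 0.24 in KO, with a difference of 0.11 ± 0.34. The inhibitory B cell receptor Cd22 went from 103.0, 80.6 and 91.4 on the untreated WT arrays to 7.0 and 5.7 at 120 min. In KO it went from 80.8, 47.6 and 89.5 to 43.4 and 43.8, a change of -0.44 ± 0.23 (adjusted p = 0.74), and the difference of response was 1.18 ± 0.32 (adjusted p = 0.377).

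The 3' to 5' ratio of beta-actin averaged 1.32 to 1.46 by group. That of Gapdh averaged 0.807 in WT and 0.817 in KO at 120 min, 0.955 and 0.913 untreated, and 0.870 and 1.02 at 30 min. In each genotype both arrays at 120 min lay below all 3 untreated ones. The 45 markers of stroma, macrophages and dendritic cells had a median change of 0.00115 in WT at 120 min, with a standard error of 0.0489 from resampling genes. That error leaves out the spread between arrays and treats the genes as independent, so it understates the uncertainty. Of the 42 probe sets that rose in WT at 120 min, 39 had an upper 95% bound in KO below the WT change itself.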
